A study of Mus musculus with 8 samples.

How the data were processed

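RNA sequencing of whole liver was analysed from 8 libraries of male C57BL/6 mice, 2 from each of 4 groups. Per the study description, 24 mice formed 4 groups of 6, and 2 livers of each group were picked at random for sequencing. Model mice received diethylnitrosamine (DEN, 0.67%) into the abdomen at 2 weeks of age and carbon tetrachloride (CCl4, 20% in olive oil) from 8 weeks until sacrifice at 22 weeks. The DWYG-M and DWYG-H groups received the same agents and, from 17 weeks, Diwu Yanggan capsules (DWYG), a herbal preparation, at 1 multiple or 2 multiples of the clinical equivalent dose. Control mice received saline in place of DEN. Per the labels' protocols, RNA was extracted with an Ambion kit, and libraries were made from 2 µg of total RNA with the SMART-Seq mRNA LP kit (Takara). The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here.

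One table of 17164 genes was used. Per the file headers, it holds a read count, an FPKM, a TPM and a normalized read count for each gene and library. The deposited read counts were treated as estimated (expected) counts, since about 90% of them were whole numbers within 0.005 (between 89.8% and 91.5% per library) and the others had fractions, as when reads that match several genes are shared out. Expected counts summed to between 17345627 and 19191382 per library. The deposited FPKM values are, per the file headers, reads scaled to gene length and library size. The deposited TPM values summed to 1000000 in each library. The signal values deposited by the authors as normalized read counts were, from their values, the expected counts rounded up and multiplied by one factor per library (0.842 to 1.26). These values were used only to read off those factors. Averages over groups in the table were not used here, and no entry lacked a gene name.

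Genes are named as in the table, by symbol and Entrez gene ID. Of the 17164 IDs, 17052 were found in a reference gene table of another mouse assembly (GRCm38.p6), 17038 of them with the same symbol. No coordinates are given, because that assembly differs from the one used by the authors. Counts of near-identical copies, such as the Mup genes and Cyp2a4 with Cyp2a5, are uncertain where reads were shared out between copies. Overlapping and antisense genes carry the same uncertainty.

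The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) on expected counts rounded to whole numbers. Libraries were scaled by TMM. Genes with an FPKM of at least 1 in at least 2 libraries were tested, which left 11606. One model of 4 groups over all 8 libraries had 4 residual degrees of freedom, a common dispersion of 0.0377 and a median of 3.98 prior degrees of freedom, and each comparison was a contrast in that model. Benjamini-Hochberg adjustment ran over all genes tested within a comparison, and an adjusted p under 0.05 was a call. Standard errors (SE) of log2 fold changes were derived from the F statistic. Adjusted p-values of genes are from edgeR unless another tool is named. The plan had assumed a table of FPKM values only, to be tested with limma, and stated that edgeR would be used if the table held counts. It did, so limma on log2(FPKM + 1) became an alternative.

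Gene lists were tested with camera with a preset correlation of 0.01 between genes, and adjusted over the lists within a comparison. Camera and fry ran on the counts and dispersions of the edgeR model, and on log2 values for TPM and FPKM. Log2 CPM with a prior count of 2 served for library correlations, principal components, list means per library and correlations of fold changes. Camera asks whether the members of a list moved further than the other genes. With an estimated correlation, camera called 0 lists in each of the 7 comparisons. Fry asks whether a list's genes moved, on balance, one way, and compares them with no other genes. In all, 38 lists with 1090 entries (1056 different genes, 34 of them on more than 1 list) were written from general knowledge of the liver, and 1052 entries were in the table. The 36 lists with at least 5 tested members were run. The remaining 2 had 0 and 3 tested members and gave no result. Counts of called members are given over all genes tested and, where stated, adjusted over the list alone.

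The genes named in the text follow a rule. In each comparison these were up to 12 higher and 12 lower genes with the largest log2 fold changes among called genes whose libraries did not overlap between groups and whose mean FPKM was at least 5 in one group. Symbols of predicted genes and of antigen receptor segments were left out. Where no gene passed, the 6 higher and 6 lower genes with the smallest p were named, as not passing. To these came 14 genes of the YAP pathway and of liver tumours, and the 4 members of each list with the smallest p. The lists, the named-gene rule, the tests and the alternatives were fixed before the data were examined, except for the alternatives and the test named as later additions. With 2 libraries per group, no exact permutation test of 1 gene can reach 0.05, so each p-value rests on the spread that edgeR shares between genes.

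Fold changes against a group with 0 reads are given as lower bounds, from 3 reads over the group. Against 1 to 3 reads, the ratio is given with an exact 95% counting interval. Both cover counting error only. Correlations of fold changes are Pearson's r across genes, which are not independent replicates. Comparisons that share the model libraries share their chance values, so each r is given beside 100 simulated sets of unchanged groups with the fitted spread, and again with the model libraries split between the fold changes. Simulated genes varied independently, so the simulated range is narrower than that of real genes. Each simulated gene had 1 spread for all groups, although the model replicates lay further apart than those of the other groups.

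Each step was tested on simulated data of 11606 genes, of which 100 changed 2-fold and 100 changed 4-fold. For model vs control, 24% of the 2-fold and 91% of the 4-fold genes were recovered, with 4 false calls among 119. The shares for DWYG-M vs model were 27% and 93% (4 false calls among 124), and for DWYG-H vs model 34% and 95% (12 among 141). For both doses vs model they were 64% and 99% (15 among 178), and for DWYG-H vs DWYG-M 37% and 96% (10 among 143). A simulated list of 30 genes raised 1.5-fold was called in each of these 5 comparisons (largest adjusted p = 9.4e-18 by camera), with at most 1 of 36 unchanged lists. The simulated genes varied independently, so this gives no rate of false list calls for genes that vary together.

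The alternatives tried were another pseudocount (0.1 in place of 1), no filter on low values, median-of-ratios scaling, TPM values, limma's eBayes with neither trend nor robust, only the groups compared, the replicate number as a block, unadjusted p with a 2-fold minimum, and leaving out each library in turn. Those on TPM or FPKM values used limma in place of edgeR for genes and no TMM scaling, so tool, unit and scaling changed together. For lists these were camera with an estimated correlation and fry. DESeq2, limma on log2(FPKM + 1), library totals without Alb and the Mup genes, and lists on TPM values were added after seeing the data. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.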

Results

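Liver RNA of male C57BL/6 mice was sequenced in 4 groups of 2 libraries each: control, model, DWYG-M and DWYG-H. Library depth was 18149462 and 17360719 counts in control, 18260254 and 19191382 in model, 18493335 and 18097161 in DWYG-M, and 17345627 and 18594473 in DWYG-H. Between 10101 and 11556 genes reached an FPKM of 1 per library. Replicates correlated across genes at r = 0.984 (control), 0.961 (model), 0.981 (DWYG-M) and 0.978 (DWYG-H). Model replicate 1 correlated more closely with each DWYG library (0.963 to 0.976) than with model replicate 2. Model replicate 2 correlated with the DWYG libraries at 0.946 to 0.966. The first principal component held 69.7% of the variance and the next held 8.42%. Major urinary protein (Mup) genes, which encode pheromone-binding proteins secreted by male liver, took 15.3% and 15.4% of all counts in the control libraries. In the model libraries the Mup share was 1.76% and 0.563%, in DWYG-M 2.09% and 3.50%, and in DWYG-H 2.06% and 2.30%. Albumin (Alb), the main plasma protein made by hepatocytes, took 6.69% and 5.19% of counts in control and 6.86% and 10.5% in model.

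**Figure D1:**
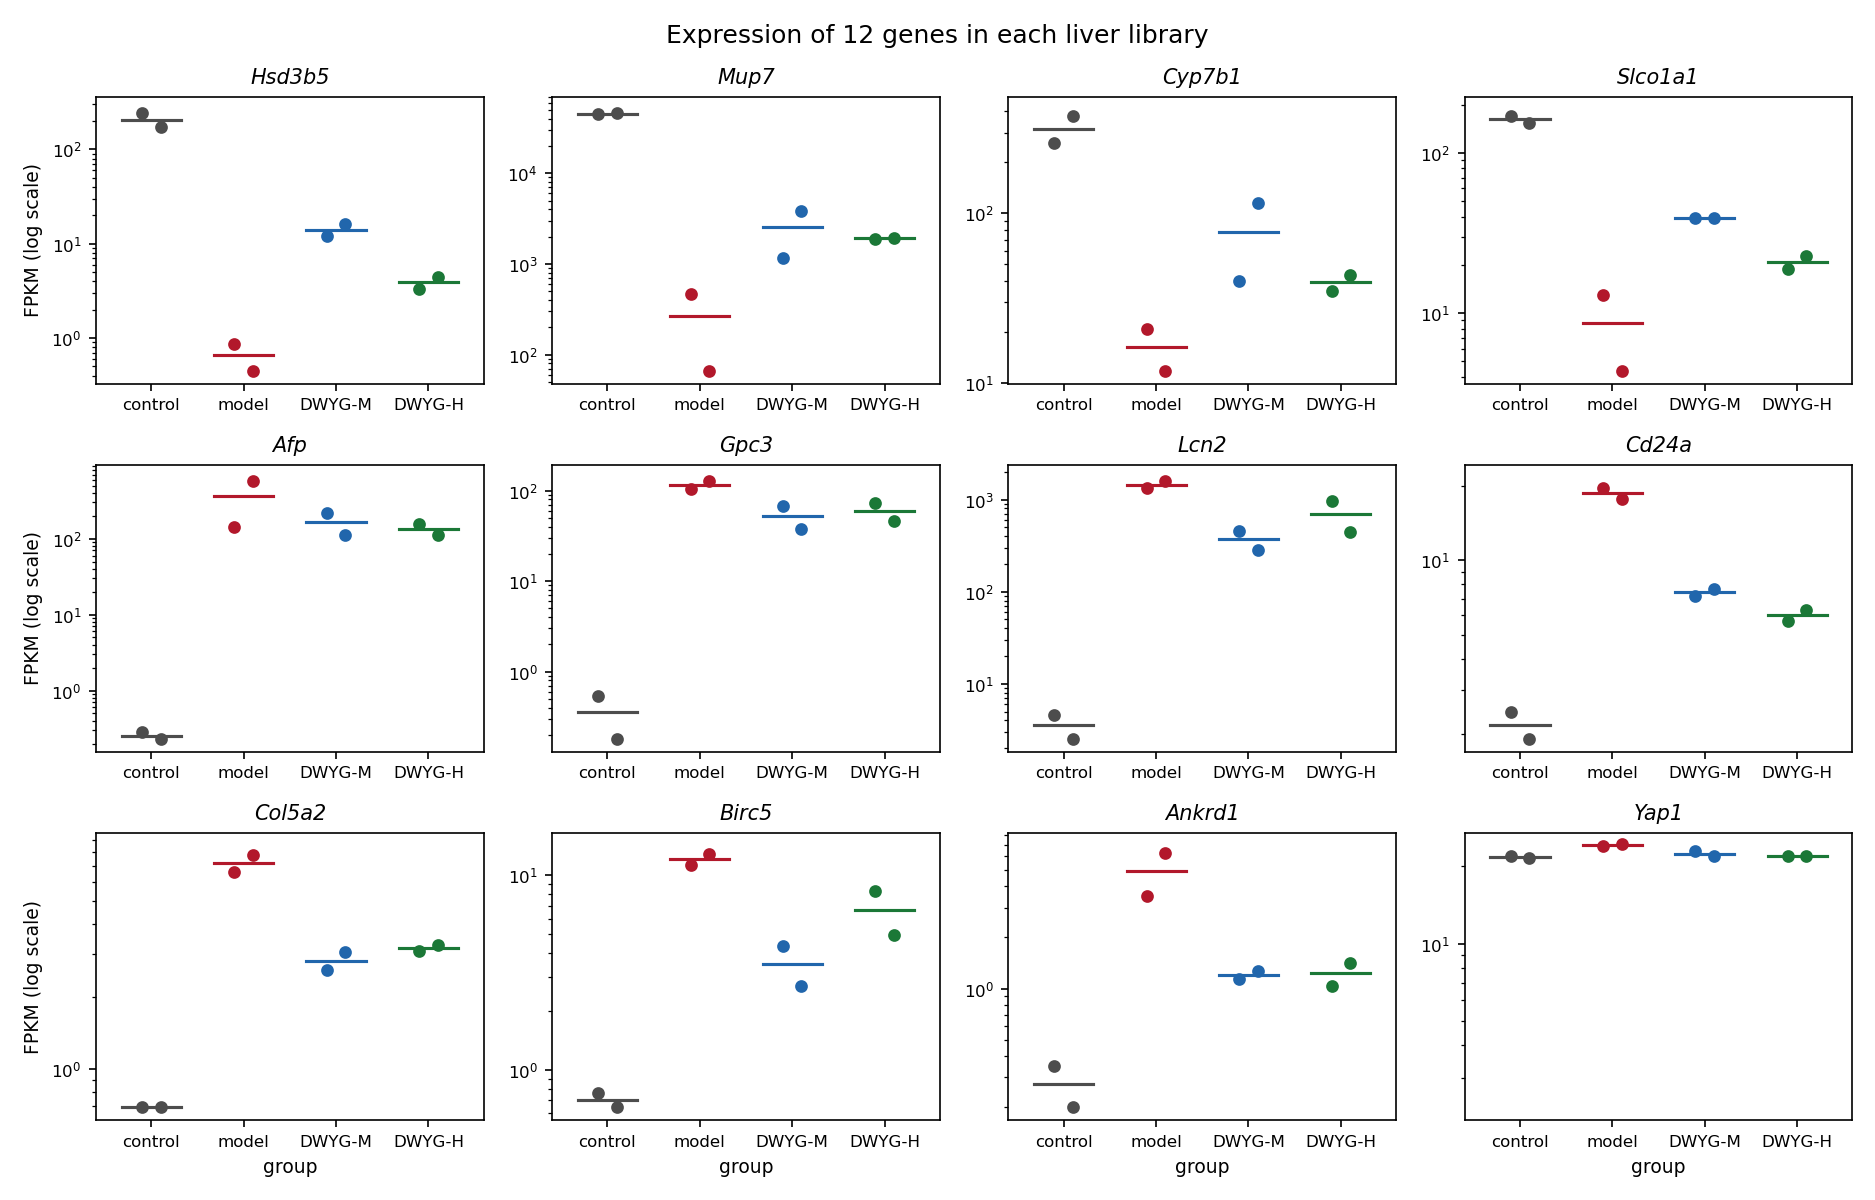
FPKM of named genes in each of the 8 libraries, grouped as control, model, DWYG-M and DWYG-H (2 libraries per group). Gpc3 had a mean of 0.360 in control, 116 in model and 59.5 in DWYG-H.

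The comparison of model vs control asked what the disease model changed in liver. Afp (Entrez 11576), which encodes the fetal plasma protein alpha-fetoprotein, rose by 10.24 on the log2 scale (SE 0.99, adjusted p = 9.7e-04, n = 2 per group), from a mean FPKM of 0.255 (SD 0.0354) to 361 (SD 308). Gpc3 (Entrez 14734), a cell-surface proteoglycan of fetal liver and liver tumours, rose by 8.07 (SE 0.55, adjusted p = 3.9e-04), from 0.360 (SD 0.255) to 116 (SD 15.5). Akr1c18 (Entrez 105349), a progesterone-reducing enzyme, rose by 10.49 (SE 0.95). Hsd3b5 (Entrez 15496), a steroid reductase of adult male liver, fell by 8.57 (SE 0.34, adjusted p = 8.1e-05), from 206 (SD 49.9) to 0.655 (SD 0.290). Each of these 4 calls stood when any single library was left out.

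Genes with almost no control reads are given as bounds. Cdh17, an intestinal and hepatobiliary cadherin, was at least 1123-fold higher in model vs control, Csn3, a milk casein, at least 208-fold, and Pglyrp1, a neutrophil granule protein, at least 53.7-fold. Cyp2a4, a female-biased steroid hydroxylase, had a ratio of 33497 (exact counting interval 6012 to 1323090) on 1 control read, and its near-identical copy Cyp2a5 makes that value uncertain. Cyp2b13, a female-biased cytochrome P450, was at least 97.2-fold higher, but its call was lost without either control library (adjusted p up to 0.0577). Among Mup genes, Mup7 fell by 7.77 on the log2 scale (SE 1.06, adjusted p = 0.00276), from a mean FPKM of 45421 (SD 936) to 264 (SD 280). Mup11, Mup15 and Mup17 gave −10.53, −10.26 and −9.63, and the close sequence identity of these copies leaves the value of each copy uncertain.

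The YAP question was asked of YAP/TAZ target genes in model vs control. Of 21 measured YAP/TAZ targets, 9 rose and 1 fell over all genes, or 13 and 1 adjusted over the list alone. The mean was 0.95 and the median 0.75 on the log2 scale (adjusted p = 1.6e-04 and adjusted p = 0.0706 with an estimated correlation). Ankrd1 (Entrez 107765), a cardiac ankyrin repeat protein driven by YAP and TEAD, rose by 3.91 (SE 0.48, adjusted p = 0.0021), from a mean FPKM of 0.275 (SD 0.106) to 4.91 (SD 1.98). Myof, a membrane-repair ferlin, rose by 2.64 (SE 0.22), Ccdc80, a matrix protein, by 2.59 (SE 0.20), and Fstl1, a secreted follistatin-like protein, by 2.89 (SE 0.27). Birc5, the mitotic survivin gene, which is on the cell cycle list and not among the 21 targets, rose by 3.56 (SE 0.39, adjusted p = 0.00143). Ccn1 and Ccn2, matricellular proteins that are standard YAP targets, gave −0.35 (adjusted p = 0.718; 0.53 on TPM values) and 2.11 (adjusted p = 0.113). Without control replicate 1 they were −1.06 and 1.35, and without control replicate 2 they were 1.07 and 3.69; Ccn1 was −0.16 without model replicate 1 and −0.54 without model replicate 2. Amotl2 gave −0.02, or 0.52 on TPM values, 0.03 without control replicate 2 and 0.12 without model replicate 2. Axl, a receptor tyrosine kinase, rose by 0.74 (adjusted p = 0.0101), a call lost without either control library (adjusted p up to 0.0870).

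Transcripts of the Hippo pathway itself were also read in model vs control. Yap1 (Entrez 22601), the transcriptional coactivator held in the cytoplasm by Hippo kinases, gave −0.11 (SE 0.14, adjusted p = 0.612), a direction that the scaling turned (0.15 on FPKM and 0.46 on TPM values, with mean FPKM 24.2 in model and 21.7 in control), as did leaving out model replicate 1 (0.01). The kinases Lats1 and Lats2 gave −0.01 and −0.03, or 0.51 and 0.43 on TPM values; Lats1 was 0.22 without model replicate 2 and 0.03 without control replicate 1, and Lats2 0.22 without control replicate 2 and 0.12 without model replicate 1. Of 25 measured Hippo pathway genes, 8 rose and 1 fell over all genes and adjusted over the list alone, with mean 0.49 and median 0.04 (adjusted p = 0.177). Wwtr1, which encodes TAZ, rose by 0.67 (SE 0.17, adjusted p = 0.0281), and Tead1, a DNA-binding partner of YAP, rose by 1.03 (adjusted p = 0.0279). Both calls were lost without control replicate 1, control replicate 2, model replicate 1 or model replicate 2 (adjusted p up to 0.149 and 0.170), and that of Wwtr1 also when only the 2 groups compared were fitted (adjusted p = 0.0675). Tead4 rose by 3.56 (adjusted p = 0.0179), a call lost without either control library or model replicate 2 (adjusted p up to 0.107).

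Collagen and matrix genes, mainly products of activated stellate cells and fibroblasts, rose in model vs control. Of 36 measured, 32 rose and 0 fell (34 and 0 adjusted over the list alone), with mean 2.63 (adjusted p = 7.6e-39 and adjusted p = 0.0706 with an estimated correlation). Col5a2, a fibrillar collagen chain, rose by 3.12 (SE 0.20), Col6a3, a microfibrillar collagen chain, by 3.59 (SE 0.26), the gelatinase Mmp2 by 3.51 (SE 0.24) and the macrophage elastase Mmp12 by 4.84 (SE 0.29). Of 24 TGF-beta signalling genes, 11 rose (11 adjusted over the list alone), among them the latent TGF-beta binding proteins Ltbp2 (4.59, SE 0.38) and Ltbp3 (3.38, SE 0.29), with mean 1.28 (adjusted p = 9.2e-07 and adjusted p = 0.0706 with an estimated correlation). Among 23 stellate and myofibroblast markers 10 rose, including Pdgfra (1.99), Pdgfrb (2.08) and Vim (2.00), and 3 fell, including Angptl6 (−1.57). Adjusted over the list alone the stellate counts were 13 and 4, with mean 0.87 (adjusted p = 0.00501 and adjusted p = 0.290 with an estimated correlation). The stellate call was lost on TPM values (adjusted p = 0.279) and with a pseudocount of 0.1 FPKM (adjusted p = 0.0712).

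Tumour, duct and proliferation markers rose together in model vs control. Of 26 liver tumour and oncofetal markers, 20 rose (22 adjusted over the list alone), with mean 4.62 (adjusted p = 9.7e-31 and adjusted p = 0.0706 with an estimated correlation), among them Cd24a, a mucin-like surface antigen (2.83), Tspan8, a tetraspanin (6.92), and Lcn2, an iron-siderophore binder (8.42). Of 17 cholangiocyte and ductular markers, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with mean 1.78 (adjusted p = 1.0e-08 and adjusted p = 0.0706 with an estimated correlation); examples were osteopontin Spp1 (3.08, SE 0.27) and the ciliary gene Bicc1 (3.54, SE 0.25). Of 39 cell cycle genes, 34 rose (35 adjusted over the list alone), with mean 2.65 (adjusted p = 2.9e-21 and adjusted p = 0.237 with an estimated correlation), such as the mitotic kinesin Kif20a (3.75) and the kinase Cdk1 (3.49). Of 25 p53 targets, 17 rose (19 adjusted over the list alone), with mean 1.97 (adjusted p = 2.0e-08 and adjusted p = 0.132 with an estimated correlation), such as the antiproliferative Btg2 (3.84) and the AKT inhibitor Phlda3 (4.61).

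Immune markers were read beside these groups in model vs control. Of 32 Kupffer cell and macrophage markers, 20 rose and 2 fell (21 and 3 adjusted over the list alone), with mean 1.30 (adjusted p = 6.4e-10 and adjusted p = 0.0952 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 8.07 (SE 0.44), the lipid receptor Trem2 by 4.48 (SE 0.38) and the endotoxin co-receptor Cd14 by 3.72 (SE 0.30). Of 27 inflammatory cytokines and NF-kB targets, 11 rose (13 rose and 1 fell adjusted over the list alone), such as the chemokine Cxcl1 (4.12), with median 1.06 (adjusted p = 5.8e-05 and adjusted p = 0.290 with an estimated correlation and adjusted p = 0.0764 on TPM values). Of 25 acute phase genes, 15 rose and 2 fell (20 and 2 adjusted over the list alone), with mean 1.54 (adjusted p = 6.1e-06 and adjusted p = 0.132 with an estimated correlation), including serum amyloid P, Apcs (2.27), and the interleukin 1 antagonist Il1rn (4.78). Of 35 interferon response genes, 12 rose (13 adjusted over the list alone), with mean 0.77 (adjusted p = 3.7e-04 and adjusted p = 0.396 with an estimated correlation). Neutrophil markers, 12 measured, had 5 that rose (7 adjusted over the list alone), including the calprotectin chain S100a9 (3.50, SE 0.75, call lost without either control library, adjusted p up to 0.104), with mean 2.64 (adjusted p = 0.00386 and adjusted p = 0.553 with an estimated correlation). The neutrophil call was lost without model replicate 1 (mean 1.57, adjusted p = 0.171) and on TPM values (adjusted p = 0.253). T and NK markers (10 measured, mean 0.46), B and plasma cell markers (7 measured, mean 1.09) and endothelial markers (26 measured, mean 0.21) did not pass as groups (adjusted p = 0.659, 0.0855 and 0.563).

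Stress-responsive genes made up the next groups in model vs control. Of 29 NRF2 targets, 13 rose and 1 fell over all genes and adjusted over the list alone, with mean 1.72 and median 0.45 (adjusted p = 1.7e-07 and adjusted p = 0.244 with an estimated correlation). The detoxifying genes Gsta1 (6.15), Cbr3 (5.46) and Nqo1 (2.57) were among them. Of 28 immediate early and heat shock genes, which respond within minutes to hours of stimulation, 17 rose (19 rose and 1 fell adjusted over the list alone), such as Ier3 (4.21) and Junb (2.03). Their mean of 1.92 (adjusted p = 2.8e-07 and adjusted p = 0.396 with an estimated correlation) was 1.00 without model replicate 1, and the group call was lost on TPM values (adjusted p = 0.0637). Endoplasmic reticulum stress genes had mean 0.38 and median −0.08 (28 measured, adjusted p = 0.883), with 4 that rose over all genes and adjusted over the list alone, such as the pseudokinase Trib3 (2.69).

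Genes with sex-biased expression in liver, set by the pattern of growth hormone release, moved in opposite directions in model vs control. Of 26 male-biased genes, 0 rose and 24 fell over all genes and adjusted over the list alone, with mean −4.19 and median −2.82 (adjusted p = 5.0e-36 and adjusted p = 0.0706 with an estimated correlation). Besides Hsd3b5 these included the glucuronosyltransferase Ugt2b38 (−4.80, SE 0.36), the organic anion transporter Slco1a1 (−4.53, SE 0.43) and the arachidonate hydroxylase Cyp4a12a (−2.35, SE 0.18). Of 16 female-biased genes, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with mean 3.95 and median 1.84 (adjusted p = 8.8e-09 and adjusted p = 0.0706 with an estimated correlation). Examples were the phenobarbital-inducible Cyp2b9 (8.90, SE 1.04), the stem cell antigen Prom1 (5.51, SE 0.51) and the fatty acid translocase Cd36 (1.87, SE 0.26). Prom1 is also on the oncofetal list, which rose too, and 7 genes of the female-biased list are also on another list.

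Metabolic groups fell in model vs control by smaller amounts, and several depended on the scaling. Nuclear-encoded oxidative phosphorylation genes, the subunits of the respiratory chain, had 0 that rose and 19 that fell of 38 (0 and 30 adjusted over the list alone), with mean −0.59 (adjusted p = 7.4e-09 and adjusted p = 0.396 with an estimated correlation) and −0.00 on TPM values. Pericentral hepatocyte genes, expressed around the central vein, had 1 that rose and 7 that fell of 27 (1 and 11 adjusted over the list alone), with mean −1.06 (adjusted p = 4.7e-05 and adjusted p = 0.396 with an estimated correlation); the ethanol-inducible Cyp2e1 fell by 2.52 (SE 0.40) and the glutamate transporter Slc1a2 by 3.97 (SE 0.53). For bile acid synthesis and transport, 1 rose and 6 fell of 26 (1 and 8 adjusted over the list alone), including the sterol hydroxylases Cyp7b1 (−4.59) and Cyp8b1 (−2.91), with mean −0.72 (adjusted p = 3.3e-04 and adjusted p = 0.396 with an estimated correlation), −0.48 without model replicate 2 and −0.19 on TPM values. Fatty acid oxidation and PPARA targets gave 2 that rose and 10 that fell of 36 (2 and 16 adjusted over the list alone), with mean −0.39 (adjusted p = 2.9e-04 and adjusted p = 0.572 with an estimated correlation), −0.13 without control replicate 2 and 0.15, the opposite sign, on TPM values, where the test against other genes kept its direction.

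Cytochrome P450 and phase II enzymes, which clear drugs and steroids, had 6 that rose and 12 that fell of 47 in model vs control (8 and 17 adjusted over the list alone), with mean −0.15 (adjusted p = 0.00549 and adjusted p = 0.553 with an estimated correlation). Their mean was −0.37 without model replicate 1, −0.04 without model replicate 2, −0.08 without control replicate 2 and 0.23 on TPM values. Cholesterol biosynthesis had 0 that rose and 3 that fell of 24 over all genes and adjusted over the list alone, with mean −0.47 (adjusted p = 0.00668 and adjusted p = 0.623 with an estimated correlation). That call was lost without control replicate 2 (−0.03, adjusted p = 0.529) or model replicate 1 (−0.26, adjusted p = 0.229), and the mean was −0.81 without control replicate 1, −0.72 without model replicate 2 and 0.16 on TPM values. Hepatocyte secretory and identity genes gave −0.09 (36 measured, adjusted p = 0.177) and ribosomal proteins 0.23 (44 measured, adjusted p = 0.171). Glycolysis genes had mean 0.45 (26 measured, adjusted p = 0.197), with Pfkp (2.47) and Pkm (1.58), 2 glycolytic enzyme forms of proliferating cells, among the 6 that rose.

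Over all genes, 2582 changed in model vs control: 1756 rose and 826 fell (68.0% higher), and 1657 of them by at least 2-fold. Limma on log2(TPM + 1), with another tool and unit and no TMM scaling, shifted the median gene by 0.54 on the log2 scale. It gave 5452 changed genes (97.5% higher). The fold changes and list means on TPM values given above for model vs control carry this shift. Limma on FPKM values shifted the median gene by 0.24 to 0.26 and gave 91.6% to 92.0% higher. Removing Alb and Mup genes from the library totals gave 79.9%. Testing only the 2 groups compared gave 1669 genes (80.5% higher). Leaving out control replicate 2 left 812 genes, control replicate 1 1099 and model replicate 2 1468 (83.1% higher).

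The comparison of DWYG-M vs model asked what the lower dose group changed in the diseased liver. Hsd3b5 was the only gene that changed: it rose by 4.50 on the log2 scale (SE 0.31, adjusted p = 0.0065, n = 2 per group), from a mean FPKM of 0.655 (SD 0.290) to 14.1 (SD 2.70), and the call stood when any library was left out but was lost when only the 2 groups compared were fitted (4.49, adjusted p = 0.0592). At unadjusted p < 0.05 edgeR gave 1468 genes, and DESeq2 called 206 genes (72 higher and 134 lower), limma on log2(FPKM + 1) 2. Leaving out model replicate 1 gave 23 genes and leaving out model replicate 2 gave 29. Yap1 gave −0.06 (adjusted p = 0.910), Wwtr1 0.00 (adjusted p = 0.999), Afp −1.15 (SE 0.62, adjusted p = 0.495) and Gpc3 −1.08 (SE 0.37, adjusted p = 0.310). The sign of Afp turned without model replicate 2 (0.35), and its value was −1.86 without model replicate 1 and −0.74 without DWYG-M replicate 2. Without model replicate 2 Yap1 was 0.05 and Wwtr1 −0.03, and without DWYG-M replicate 2 Wwtr1 was −0.01.

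As groups, 22 of the lists passed in DWYG-M vs model, 8 higher and 14 lower; 5 passed the rotation test (fry) and 0 with an estimated correlation. YAP/TAZ targets fell as a group, with mean −0.56 and 19 of 21 values negative (adjusted p = 1.9e-06 and adjusted p = 0.0952 with an estimated correlation). Over all genes 0 of the 21 were called, and adjusted over the list alone 1 rose and 8 fell. Ankrd1 (adjusted p = 0.213) had a mean FPKM of 1.21 (SD 0.0919) against 4.91 in model. Fstl1 gave −1.11 (SE 0.25, and −0.72 without model replicate 2) and Ccn1 −1.06 (adjusted p = 0.516). Smaller values were those of Ccn2 (−0.38, and −2.03 to 0.37 over the leave-outs), Amotl2 (−0.23) and Axl (−0.36). Birc5, on the cell cycle list and not among the 21 targets, gave −1.56 (adjusted p = 0.213). Collagen and matrix genes fell as a group with mean −0.86 (adjusted p = 1.5e-23 and adjusted p = 0.120 with an estimated correlation), 0 called over all genes and 23 of 36 lower adjusted over the list alone; the crosslinking enzyme Lox gave −1.72 (SE 0.26) and Col5a2 −1.30 (SE 0.18, adjusted p = 0.197). TGF-beta signalling genes had mean −0.48 (adjusted p = 1.7e-05 and adjusted p = 0.120 with an estimated correlation). Stellate markers had mean −0.43 (adjusted p = 0.0419 and adjusted p = 0.375 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0587), control replicate 2 (0.0562), model replicate 2 (−0.19, 0.331) or DWYG-M replicate 1 (0.113), on TPM values (0.152) and with a pseudocount of 0.1 FPKM (0.122).

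Proliferation, duct and macrophage markers also fell as groups in DWYG-M vs model, each with 0 members called over all genes. Cell cycle genes had mean −1.13 (adjusted p = 2.0e-22 and adjusted p = 0.234 with an estimated correlation), with 23 of 39 lower adjusted over the list alone; Kif20a gave −1.88. For cholangiocyte and ductular markers the mean was −1.02 (adjusted p = 3.3e-10 and adjusted p = 0.0952 with an estimated correlation), with 1 higher and 11 lower of 17 adjusted over the list alone; the ductal keratin Krt19 gave −1.97 (SE 0.44) and the mucin Muc1 −1.73 (SE 0.34). Oncofetal markers had mean −0.81 (adjusted p = 2.3e-09 and adjusted p = 0.234 with an estimated correlation), or −0.38 without model replicate 2. Macrophage markers had mean −0.57 (adjusted p = 8.4e-13 and adjusted p = 0.120 with an estimated correlation), with 17 of 32 lower adjusted over the list alone; Cd14 gave −1.56 (SE 0.26) and the integrin Itgam −1.34 (SE 0.23). Immediate early genes had mean −1.53, all 28 values negative (adjusted p = 1.2e-17 and adjusted p = 0.234 with an estimated correlation), but −0.59 without model replicate 1. NRF2 targets had mean −0.44 (adjusted p = 8.7e-05 and adjusted p = 0.311 with an estimated correlation), a call lost without model replicate 1 (−0.21, adjusted p = 0.169).

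Male-biased genes rose as a group in DWYG-M vs model, with mean 1.53 and 24 of 26 values positive (adjusted p = 9.5e-28 and adjusted p = 0.0952 with an estimated correlation). Over all genes 1 was called, Hsd3b5, and 14 were higher adjusted over the list alone; Slco1a1 gave 2.28 (SE 0.39) and Cyp4a12a 1.48 (SE 0.18, adjusted p = 0.167). Female-biased genes had mean −0.60 (adjusted p = 0.00824 and adjusted p = 0.234 with an estimated correlation), a call lost without model replicate 2 (−0.12, adjusted p = 0.464) or DWYG-M replicate 2 (−0.45, adjusted p = 0.126), and the mean was −0.98 without DWYG-M replicate 1. Oxidative phosphorylation genes had mean 0.33 with all 38 values positive and 0 called over all genes or adjusted over the list alone (adjusted p = 3.7e-09 and adjusted p = 0.375 with an estimated correlation), or 0.16 without DWYG-M replicate 2. Pericentral genes had mean 0.71 (adjusted p = 1.2e-07 and adjusted p = 0.234 with an estimated correlation), 1.13 without model replicate 1 and 0.36 without DWYG-M replicate 2; Cyp2e1 gave 1.56 (SE 0.38).

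The comparison of DWYG-H vs model asked the same of the higher dose group. By edgeR 0 genes changed in this comparison, with 985 at unadjusted p < 0.05; DESeq2 called 120 (38 higher and 82 lower) and limma on log2(FPKM + 1) 3, all lower. The smallest adjusted p was that of Cd24a (Entrez 12484), at −1.57 (SE 0.16, adjusted p = 0.0562, n = 2 per group), with a mean FPKM of 6.00 against 18.6 in model. Mmp7 (Entrez 17393), the ductal matrilysin, gave −2.85 (adjusted p = 0.113) and Hsd3b5 2.65 (SE 0.32, adjusted p = 0.113). Yap1 gave −0.09 (adjusted p = 0.928), Wwtr1 −0.16 (adjusted p = 0.860), Afp −1.43 (adjusted p = 0.590) and Gpc3 −0.91 (adjusted p = 0.571). Without model replicate 2 the signs of Afp (0.07) and Yap1 (0.02) turned, and without model replicate 1 Afp was −2.15. Wwtr1 was −0.32 without DWYG-H replicate 1 and −0.01 without DWYG-H replicate 2. Leaving out model replicate 1 gave 7 genes, model replicate 2 17 and DWYG-H replicate 1 1.

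As groups, 25 of the lists passed in DWYG-H vs model, 10 higher and 15 lower; 0 passed the rotation test (fry) and 0 with an estimated correlation. YAP/TAZ targets fell as a group with mean −0.61 and 18 of 21 values negative (adjusted p = 3.8e-08 and adjusted p = 0.0722 with an estimated correlation and adjusted p = 0.0504 by fry), with 0 called over all genes and 7 lower adjusted over the list alone. Ankrd1 gave −1.96 (SE 0.40, adjusted p = 0.250), Fstl1 −1.18 (SE 0.25, and −0.79 without model replicate 2) and Ccn1 −1.13 (adjusted p = 0.664). Ccn2 gave −0.85, Axl −0.33 and Amotl2 0.10, or −9.8e-04 for Amotl2 on TPM values. Hippo pathway genes had mean −0.20 (adjusted p = 0.0413 and adjusted p = 0.369 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0513), control replicate 2 (0.0531), model replicate 1 (0.404) or DWYG-H replicate 2 (0.311). Collagen and matrix genes had mean −0.79 (adjusted p = 3.4e-25 and adjusted p = 0.148 with an estimated correlation), with 22 of 36 lower adjusted over the list alone, among them Col5a2 (−1.12, SE 0.18) and Lox (−1.52, SE 0.25). Cholangiocyte and ductular markers had mean −1.01 (adjusted p = 4.1e-14 and adjusted p = 0.0722 with an estimated correlation), with 8 of 17 lower adjusted over the list alone; Krt19 gave −2.35 (SE 0.46). Stellate markers had mean −0.58 (adjusted p = 2.0e-05 and adjusted p = 0.214 with an estimated correlation), or −0.34 without model replicate 2. TGF-beta signalling genes had mean −0.49 (adjusted p = 4.4e-07 and adjusted p = 0.109 with an estimated correlation).

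Other groups in DWYG-H vs model depended more on single libraries. Cell cycle genes had mean −0.61 (adjusted p = 7.4e-10 and adjusted p = 0.336 with an estimated correlation), −1.12 without DWYG-H replicate 1 and −0.25 without DWYG-H replicate 2, with 0 lower adjusted over the list alone. Macrophage markers had mean −0.19 (adjusted p = 0.00151 and adjusted p = 0.302 with an estimated correlation), a call lost without model replicate 1 (−0.06, adjusted p = 0.245). Acute phase genes had mean −0.41 (adjusted p = 0.00185 and adjusted p = 0.291 with an estimated correlation), and the sign turned without model replicate 1 (0.05, adjusted p = 0.404). T and NK markers had mean 0.62 with all 10 values positive (adjusted p = 0.0160 and adjusted p = 0.384 with an estimated correlation), a call lost without model replicate 1 (adjusted p = 0.0975), model replicate 2 (0.0542) or DWYG-H replicate 2 (−0.06, 0.889); without DWYG-H replicate 1 the mean was 0.96. Immediate early genes had mean −1.37 (adjusted p = 1.7e-17 and adjusted p = 0.257 with an estimated correlation), or −0.44 without model replicate 1. Fatty acid and triglyceride synthesis genes had mean 0.56 (adjusted p = 1.9e-06 and adjusted p = 0.285 with an estimated correlation), or 0.15 without DWYG-H replicate 2; the carbohydrate-response factor Mlxipl gave 1.18 (1.80 without model replicate 1 and 0.74 without model replicate 2). Male-biased genes had mean 1.07 with 23 of 26 positive (adjusted p = 1.4e-14 and adjusted p = 0.148 with an estimated correlation) and 1 higher adjusted over the list alone.

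With both doses vs model, 4 libraries against 2, the question was what the dose groups shared. Hsd3b5 rose by 3.57 (SE 0.30, adjusted p = 0.0200), while Cd24a fell by 1.42 (SE 0.13, adjusted p = 0.0200), from a mean FPKM of 18.6 (SD 1.41) to 6.72 (SD 0.891). Mmp7 fell by 2.51 (SE 0.27, adjusted p = 0.0447), from 18.4 (SD 1.75) to 3.19 (SD 1.16). Ehf, an epithelial ETS factor chosen for mention after its values were seen, fell by 1.91 (SE 0.18, adjusted p = 0.0200). The Hsd3b5 call was lost without DWYG-M replicate 2, DWYG-H replicate 1 or DWYG-H replicate 2 (adjusted p up to 0.0871), those of Cd24a (up to 0.192) and Ehf without any of the 4 DWYG libraries, and that of Mmp7 in every leave-out of a control or DWYG library or of model replicate 2 (up to 0.298). Limma on log2 FPKM with a pseudocount of 0.1 ended the calls of Mmp7 (adjusted p = 0.0577) and Ehf, and fitting only the groups compared that of Mmp7 (adjusted p = 0.0732). These 4 were all the genes changed by edgeR, with 1618 at unadjusted p < 0.05; DESeq2 called 321, limma on log2(FPKM + 1) 9, limma on log2(TPM + 1) 29 and edgeR on the data without a filter 30. Leaving out model replicate 1 gave 69 genes, model replicate 2 38, DWYG-M replicate 1 1, and DWYG-M replicate 2, DWYG-H replicate 1 or DWYG-H replicate 2 0.

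In both doses vs model 23 lists passed, 8 higher and 15 lower; 3 passed by fry and 0 with an estimated correlation. YAP/TAZ targets had mean −0.59 (adjusted p = 5.2e-08 and adjusted p = 0.0826 with an estimated correlation and adjusted p = 0.0321 by fry), with 0 called over all genes and 1 higher and 8 lower adjusted over the list alone. Ankrd1 gave −1.98 (SE 0.32, adjusted p = 0.101) and Yap1 −0.07 (adjusted p = 0.853; 0.04 without model replicate 2). Collagen and matrix genes had mean −0.83 (adjusted p = 1.1e-27 and adjusted p = 0.127 with an estimated correlation), with 26 of 36 lower adjusted over the list alone. Cell cycle genes had mean −0.87 (adjusted p = 4.2e-18 and adjusted p = 0.219 with an estimated correlation) and cholangiocyte markers −1.02 (adjusted p = 4.4e-14 and adjusted p = 0.0826 with an estimated correlation). Male-biased genes had mean 1.30 (adjusted p = 4.8e-21 and adjusted p = 0.102 with an estimated correlation), with 1 called over all genes and 16 higher adjusted over the list alone. Macrophage markers had mean −0.38 (adjusted p = 2.7e-08 and adjusted p = 0.188 with an estimated correlation), or −0.25 without model replicate 1, and the inflammatory call (−0.37) was lost without DWYG-H replicate 1 (−0.23, adjusted p = 0.173).

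**Figure D2:**
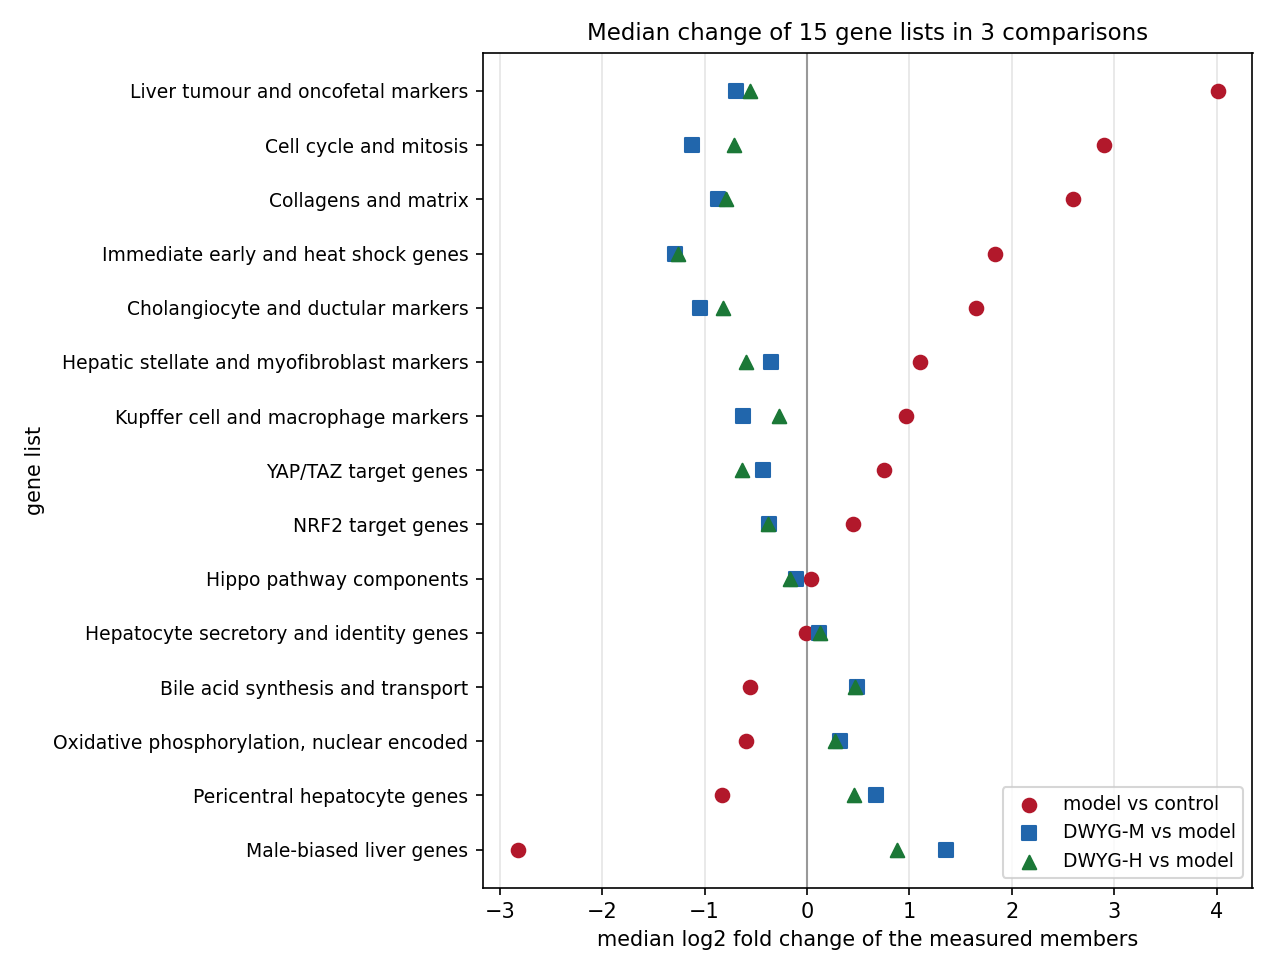
Median log2 fold change of selected gene lists in model vs control, DWYG-M vs model and DWYG-H vs model (2 libraries per group). YAP/TAZ targets had a median of 0.75 in model vs control, −0.43 in DWYG-M vs model and −0.64 in DWYG-H vs model.

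DWYG-H vs DWYG-M asked for a difference between the doses. By edgeR 0 genes changed, with 193 at unadjusted p < 0.05 against 580 by chance; DESeq2 called 5 (2 higher and 3 lower), and leaving out DWYG-H replicate 1 gave 2. Cyp4a12a had the smallest adjusted p, at −1.40 (adjusted p = 0.534), with a mean FPKM of 34.6 (SD 2.11) in DWYG-H against 91.5 (SD 15.8) in DWYG-M, and Hsd3b5 gave −1.84 (adjusted p = 0.534). YAP/TAZ targets had mean −0.05 (adjusted p = 0.785), Yap1 gave −0.03 and Ankrd1 0.04 (−0.04 without DWYG-M replicate 1 and −0.19 without DWYG-H replicate 2). Inflammatory genes had mean 0.80 and male-biased genes −0.46, and both lists passed, but 0 of the 18 lists that passed did so with an estimated correlation (smallest adjusted p = 0.309 with an estimated correlation) or by fry. Without DWYG-H replicate 2 the inflammatory mean was 0.05, and without DWYG-M replicate 2 the male-biased mean was −0.02.

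DWYG-M vs control and DWYG-H vs control asked how far the dose groups remained from normal liver. Gpc3 was higher by 6.98 (SE 0.53, adjusted p = 0.00215) in DWYG-M and 7.15 (SE 0.53, adjusted p = 0.00123) in DWYG-H, and Hsd3b5 was lower, at −4.08 (SE 0.26, adjusted p = 0.00128) and −5.92 (SE 0.29, adjusted p = 4.0e-04). Lcn2 was at 6.47 and 7.42 and Gpnmb at 6.86 and 7.78, and these calls stood in all leave-outs. Afp was at 9.09 and 8.81, with the call lost without either control library in DWYG-M vs control (adjusted p up to 0.0635) and without control replicate 2 in DWYG-H vs control (adjusted p = 0.0542). Birc5 was at 1.99 and 2.80; the calls were lost without control replicate 1, control replicate 2 or DWYG-M replicate 1 (adjusted p up to 0.197) and without either control library (adjusted p up to 0.0770). Ankrd1, at 1.91 and 1.95, did not pass (adjusted p = 0.0819 and 0.0601), and neither did Yap1 (−0.17 and −0.20, or 0.28 and 0.28 on TPM values). Ccn1 was at −1.41 and −1.48, or −0.57 and −0.62 on TPM values, below control in both dose groups. Its value in model vs control was −0.35 and turned with the control library, so its fall against model was not the return of a clear rise. Cdh17 was at least 525-fold and at least 519-fold above control.

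Against control, collagen and matrix genes had mean 1.77 in DWYG-M (27 of 36 rose, 32 adjusted over the list alone, adjusted p = 7.9e-36 and adjusted p = 0.0903 with an estimated correlation). In DWYG-H the mean was 1.84 (28 rose, 31 adjusted over the list alone, adjusted p = 1.5e-31 and adjusted p = 0.119 with an estimated correlation). Cell cycle genes had mean 1.52 in DWYG-M (7 of 39 rose, 25 adjusted over the list alone, adjusted p = 4.1e-13 and adjusted p = 0.366 with an estimated correlation) and 2.04 in DWYG-H (24 rose, 31 adjusted over the list alone, adjusted p = 1.2e-19 and adjusted p = 0.294 with an estimated correlation). Male-biased genes had mean −2.67 (16 of 26 fell, 23 adjusted over the list alone, adjusted p = 1.0e-33 and adjusted p = 0.0802 with an estimated correlation) and −3.13 (19 fell, 24 adjusted over the list alone, adjusted p = 9.2e-40 and adjusted p = 0.119 with an estimated correlation). YAP/TAZ targets had mean 0.39 in DWYG-M, with 3 that rose and 5 adjusted over the list alone (adjusted p = 0.0387 and adjusted p = 0.301 with an estimated correlation). In DWYG-H their mean was 0.34 (adjusted p = 0.0748). The size depended on the control library: the mean log2 CPM of the list was 3.14 and 3.41 in control, against 3.64 and 3.66 in DWYG-M.

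In number, 575 genes changed in DWYG-M vs control (505 rose and 70 fell, 87.8% higher) and 892 in DWYG-H vs control (765 rose and 127 fell, 85.8% higher). Without control replicate 2 these counts were 39 and 77, without control replicate 1 52 and 151, without DWYG-M replicate 1 184 in DWYG-M vs control, and without DWYG-H replicate 1 or 2 323 and 423 in DWYG-H vs control. Limma on log2(TPM + 1) shifted the median gene by 0.43 and 0.44 and gave 2840 and 3379 genes.

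Fold changes were then compared across all genes. Genes are not independent, and a shared arm alone gives a correlation, so the main values stand beside a simulated value with no group changed. The simulated sets lack the effect of the model as well as that of dose. Their r is therefore not the value for an absent dose effect alone. Each simulated gene also had 1 spread for all groups. The median absolute log2 difference between replicates was 0.310 in model, against 0.183 to 0.222 in the other groups. With that wider model spread, simulated values for arms that share model libraries would lie further from 0. This was not simulated, so the differences from simulated values are overstated to an unknown degree. Model vs control and DWYG-M vs model, which share the model libraries, correlated at r = −0.744, against a simulated mean of −0.498 (lowest −0.539); the covariance was −0.360 against −0.0530, a difference of −0.307. With the model libraries split so that the arms shared none, r was −0.586 and −0.384. For DWYG-H the correlation was −0.640, against −0.498 (lowest −0.549), with a covariance difference of −0.228, and −0.474 and −0.273 after the split. The 2 dose groups against model correlated at 0.821, against 0.502 simulated (highest 0.536), with a covariance difference of 0.0981, and 0.276 and 0.300 after the split.

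**Figure D3:**
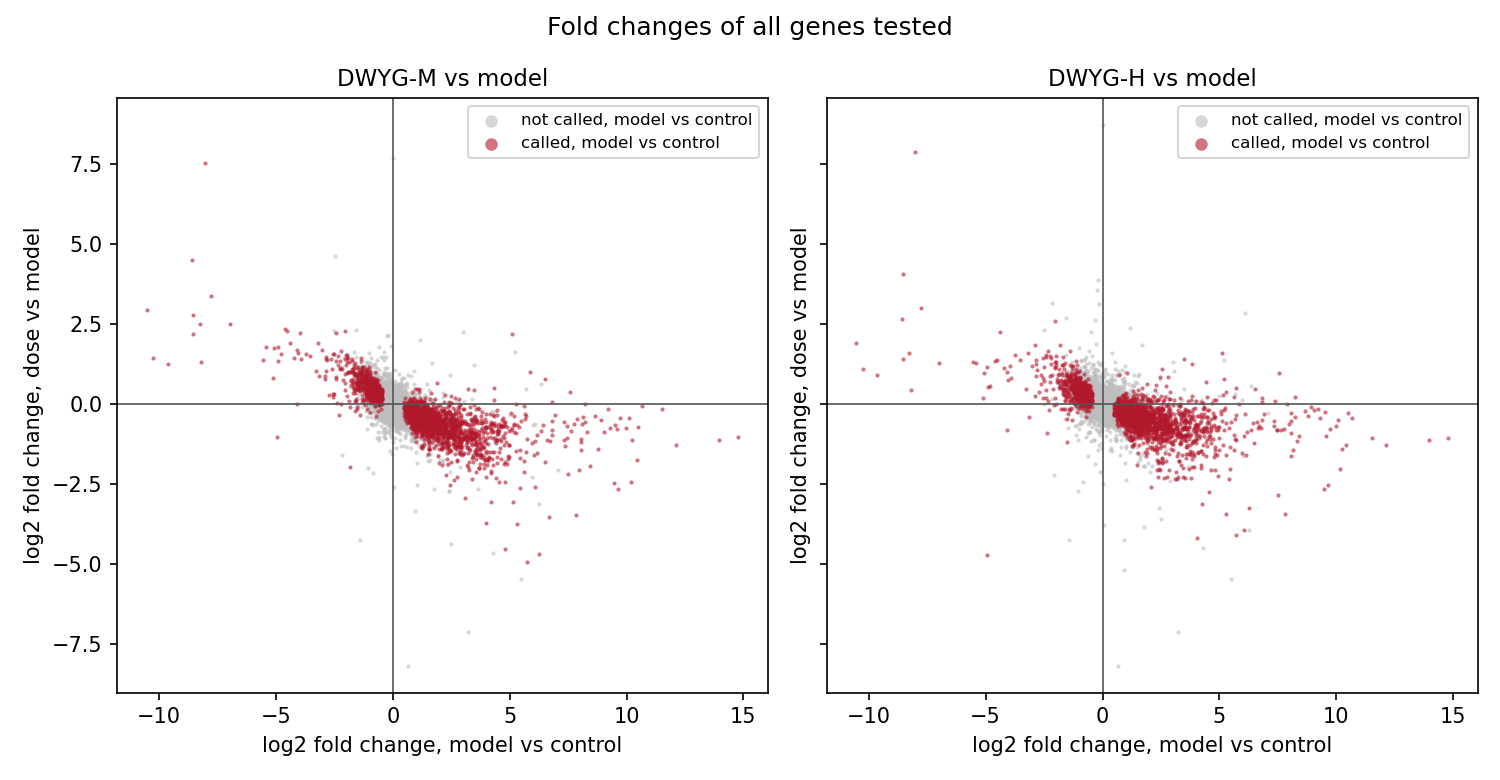
Log2 fold change of each gene in model vs control (horizontal) against DWYG-M vs model and DWYG-H vs model (vertical), 2 libraries per group. The correlation was −0.744 for DWYG-M and −0.640 for DWYG-H, with the model libraries shared by both axes.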

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

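The test of Y-linked genes and the test of model replicate 2 against the spread of DWYG libraries were chosen only after the result was seen.

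Of 36 gene lists, 18 were set apart for a closer look because they passed camera with the preset correlation in DWYG-H vs DWYG-M, 9 higher and 9 lower. In that comparison edgeR called 0 genes, and 193 had an unadjusted p < 0.05 against 580 by chance. The same camera setting gave the 22, 25 and 23 lists that passed in DWYG-M, DWYG-H and both doses vs model, so those calls carry the same doubt. Higher in DWYG-H were inflammatory cytokines and NF-kB targets (mean log2 0.80), T and NK cell markers (0.71), cell cycle genes (0.52), acute phase genes (0.44), macrophage markers (0.38), fatty acid and triglyceride synthesis (0.34), B and plasma cell markers (0.33), interferon response (0.29) and p53 targets (0.18). Lower were oxidative phosphorylation (−0.0698), fatty acid oxidation (−0.0878), NRF2 targets (−0.11), endothelial markers (−0.13), stellate markers (−0.15), cytochrome P450 enzymes (−0.21), pericentral genes (−0.22), circadian clock genes (−0.37) and male-biased genes (−0.46). The adjusted p by camera ran from 2.1e-14 (macrophage markers and male-biased genes) to 0.0473 (oxidative phosphorylation). With an estimated correlation the smallest was 0.309, so none of these 18 differences passed when the correlation among the members was estimated from the data. Many also rested on single libraries: without DWYG-H replicate 2 the mean of T and NK markers was 0.02 and that of interferon genes 0.02, and without DWYG-H replicate 1 that of cell cycle genes was −0.00. With 2 libraries per dose, these list differences rest on few animals.

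The DWYG livers lay between model and control in expression. A shared set of model libraries was tested as the cause: with separate model libraries in each arm the weakest of 4 correlations was still −0.273, below the lowest simulated value of −0.0540. A single unusual model library was tested too: without model replicate 2 the covariance was −0.279 and without model replicate 1 it was −0.517. These lay below the lowest simulated values, −0.117 and −0.113. As a correlation, the value without model replicate 2 (−0.625) was no stronger than the simulated mean (−0.729), but the simulated sets also lack the effect of the model. Simulated genes varied independently, so the simulated ranges are too narrow to exclude chance differences between the few animals. They also had 1 spread for all groups, although model replicates lay further apart, so the simulated covariances lie too close to 0. More hepatocytes in the piece of liver sampled would lower the markers of all other cell types alike. The list medians in both doses vs model ran from −0.96 (cholangiocyte) through −0.46 (macrophage) and −0.45 (stellate) to 0.04 (endothelial). The gap of 1.00 had an SE of 0.281 over genes, which does not measure the spread between animals. Its lists were picked as the highest and lowest of 4. These values argue at most against more hepatocytes as the only cause. Chance differences between animals stay open, as do more hepatocytes together with another change, and a loss of duct-like cells or macrophages themselves. So do a milder injury in the DWYG animals from a source other than the treatment, and, as a hypothesis only, an effect of the treatment.

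Male-biased genes were lower and female-biased genes higher in model livers than in control livers. Female animals among the model group were tested for: each of 4 Y-linked genes was above an FPKM of 1 in 8 of 8 libraries, so 0 libraries did not match the labels. Reads shared among near-identical Mup copies do not account for the whole fall of male-biased genes. The 18 male-biased members that are not Mup genes had a median of −2.30 (SE 0.737 over genes), and 16 of them were lower and called. A lower share of hepatocytes would lower other hepatocyte genes as far, but their median was −0.01, a gap of 2.29 (SE 0.753 over genes). Errors over genes do not measure the spread between animals. The Mup and hepatocyte tests used no female-biased genes, so they leave the cause of the female-biased rise open. A loss of the male pattern of growth hormone signalling in the injured liver stays open as a hypothesis, and it was not tested here.

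Immediate early and heat shock genes were higher in model livers than in DWYG livers, with a mean in both doses vs model of −1.45. Infiltrating myeloid cells were tested as the source: model replicate 1 exceeded model replicate 2 by 1.37 on the immediate early list but by 0.21 on the macrophage list. Neutrophil markers differed by 1.19 between the model libraries, and their mean in both doses vs model was 0.25 (SE 0.231 over genes). The DWYG libraries lay at 1.35 to 2.20, with DWYG-M replicate 2 highest, against 2.05 and 0.86 in model replicates 1 and 2. The mean thus depended on the model library, so whether neutrophil markers fell with the immediate early list is not decided. Model replicate 1 alone as the source stays open: without it the mean was −0.52 (SE 0.139 over genes), and without model replicate 2 it was −1.89. Leaving out model replicate 1 left 1 model library. The DWYG mean minus that library was −0.55, with an SE of 0.366 from the spread between libraries. The error over genes set beforehand was therefore too narrow a yardstick. A difference in how the pieces of liver were handled before freezing also stays open and was not tested, and no batch or collection time is given in the sources used here.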

How the results depend on the processing

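Among the alternatives, limma on log2(FPKM + 1), DESeq2, library totals without Alb and Mup genes, and lists on TPM values were chosen only after results were seen.

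With 2 libraries per group, leaving out a library of a compared group leaves 1 library of that group. That library is then assumed to vary like the other groups. Leave-outs of a library outside the comparison keep every compared library and change only the shared spread and the scaling. They are counted too, so the counts of kept calls overstate how well calls survive the loss of a compared library. For the 107 list calls other than those of YAP/TAZ targets, over 8 leave-outs each, 789 calls were kept, 60 ended and 7 reversed, counted by the direction of camera, which sets a list against the other genes. Of 2904 calls of named genes so tested, 2299 were kept and 605 ended, and 142 were added among 6128 values that had not passed. Reversed by camera were, in DWYG-H vs DWYG-M without DWYG-M replicate 2, p53 targets (−0.0276), pericentral genes (0.12), fatty acid oxidation (0.08) and oxidative phosphorylation (0.10), and, without DWYG-H replicate 2, fatty acid synthesis (−0.0651), fatty acid oxidation (0.17) and B and plasma cell markers (−0.0406). Among the ended calls the sign of the mean turned too, while camera kept its direction, in DWYG-H vs model for acute phase genes (0.05 without model replicate 1), T and NK markers (−0.06) and cytochrome P450 enzymes (−0.03, both without DWYG-H replicate 2), and in DWYG-H vs DWYG-M without DWYG-H replicate 1 for cell cycle genes (−5.0e-04) and p53 targets (−0.0160). At the other end of the leave-outs these lists reached 0.52 (p53), −0.47 (pericentral), −0.49 (fatty acid oxidation), −0.22 (oxidative phosphorylation), 0.56 (fatty acid synthesis) and 0.60 (B and plasma cell). The number of genes changed ran from 812 to 2845 in model vs control, 1 to 29 in DWYG-M vs model, 0 to 17 in DWYG-H vs model, 0 to 69 in both doses vs model, 0 to 2 in DWYG-H vs DWYG-M, 39 to 844 in DWYG-M vs control and 77 to 1248 in DWYG-H vs control. Reversal correlations ran from −0.809 to −0.579 (DWYG-M) and from −0.733 to −0.520 (DWYG-H), and the correlation between doses from 0.720 to 0.895. Without model replicate 2 the reversal correlations were −0.655 (DWYG-M) and −0.538 (DWYG-H). They were no stronger than the simulated mean for unchanged groups (−0.665 for each). The covariances were below the simulated means (differences of −0.213 and −0.133). Those simulated means used 1 spread for all groups, although the model replicates lay further apart. Only 11606 of 17164 genes reached an FPKM of 1 in at least 2 libraries, so little can be said of neutrophil, T, NK, B and plasma cell markers, whether for depth or for low expression in whole liver, which was not tested.

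With limma on log2(TPM + 1), which changes the tool as well as the unit, 5452 genes changed in model vs control, 2 in DWYG-M vs model, 1 in DWYG-H vs model, 29 in both doses vs model, 2840 in DWYG-M vs control and 3379 in DWYG-H vs control. Limma on log2 FPKM with a pseudocount of 0.1, again another tool and unit, gave 3 in DWYG-M vs model, 1086 in DWYG-M vs control and 1444 in DWYG-H vs control, and ended 6 list calls. Without a filter, 4 changed in DWYG-H vs model and 30 in both doses vs model. Limma with neither trend nor robust settings gave 2, 2 and 25, and limma on log2(FPKM + 1) 2, 3 and 9, for DWYG-M vs model, DWYG-H vs model and both doses vs model. DESeq2 gave 206, 120, 321 and 5 for these and DWYG-H vs DWYG-M, and 1007 and 1385 against control. Unadjusted p < 0.05 with at least 2-fold gave 427, 317, 365 and 61, and 1048 in DWYG-M vs control. Testing only the groups compared gave 1669 in model vs control, where fewer libraries inform the spread. For the others the cause was not tested.

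For YAP/TAZ targets, an estimated correlation ended the calls in model vs control (mean 0.95), DWYG-M vs model (−0.56), DWYG-H vs model (−0.61) and both doses vs model (−0.59), with adjusted p = 0.0706 to 0.0952, and left 0 of the other 107 list calls in 5 comparisons. Fry ended the YAP/TAZ call in DWYG-H vs model (−0.61, adjusted p = 0.0504) and left 5 lists in DWYG-M vs model, 0 in DWYG-H vs model, 3 in both doses vs model and 0 in DWYG-H vs DWYG-M. Median-of-ratios scaling and totals without Alb and Mup genes ended 0 list calls, and lists on TPM values lost 5 of those 107. Reversal correlations with the model libraries split were −0.586 and −0.384 (DWYG-M) and −0.474 and −0.273 (DWYG-H), and the correlation between doses was 0.276 and 0.300. Over genes called in model vs control, chosen for their change in the same model libraries, they were −0.808, −0.723 and 0.868, against simulated means of −0.503, −0.502 and 0.503.

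The libraries share only a replicate number, and deviations of libraries with the same number correlated at −0.143 to 0.255. With the replicate number as a block, which leaves 3 residual degrees of freedom in place of 4, 0 genes changed in DWYG-M vs model, 0 in both doses vs model and 2682 in model vs control, and 0 list calls ended. The adjusted p of Hsd3b5 under the block was 0.0596 in DWYG-M vs model.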

Other observations

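The genes in this paragraph were chosen after their values were seen, and no set of genes of other epithelia was tested. In model vs control, Tspan8, a tetraspanin of gut and pancreas, rose by 6.92 on the log2 scale, and Sprr1a, a cornified envelope protein of squamous epithelium, was at least 82.8-fold higher. Ehf, an epithelial ETS factor, had a mean FPKM of 0.235 in control, 2.70 in model, 0.880 in DWYG-M and 0.535 in DWYG-H.

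Replicates lay further apart in the model group than in the others. The median absolute log2 difference between replicates was 0.310 in model, against 0.222 in control, 0.183 in DWYG-M and 0.199 in DWYG-H. The model libraries differed on the immediate early list by 1.37 and on neutrophil markers by 1.19, but by 0.21 on macrophage markers.

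The hypothesis was that the lower YAP/TAZ targets of the DWYG livers were part of a general fall of mesenchymal and wound-healing genes and not a separate fall of YAP activity. If so, the targets would change like collagen and matrix genes, which share 0 genes with them. In both doses vs model the YAP/TAZ mean was −0.59 and the matrix mean −0.83. The difference of 0.24 (SE 0.156 over genes, not between animals) is within 2 standard errors. In absolute size this is consistent with a general fall. In model vs control the targets rose less than the matrix genes, a difference of −1.68 (SE 0.366 over genes). As a share of that rise the targets thus fell further, and that share was not tested. Yap1 RNA did not pass in any comparison, and YAP protein, its phosphorylation and its place in the cell were not analysed here, so the hypothesis stays open.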
